A study of Homo sapiens with 12 samples.

How the data were processed

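Transcript levels were measured in 2 human cell lines on Affymetrix U133 Plus 2 arrays, on which 1 biotin-labelled RNA sample is hybridised per array. HCT116 is a colorectal carcinoma line and MCF7 is a breast adenocarcinoma line. Per the labels, each line was stably transfected with a plasmid that drives a hairpin RNA from a U6 promoter, directed at exon 17 of TOP1 (siTOP1), or with a control construct (siControl). Resistant cells were selected with hygromycin B at 600 µg/ml for HCT116 and 400 µg/ml for MCF7. Total RNA was amplified and labelled as biotinylated antisense RNA before hybridisation. The 12 arrays formed 4 groups, with 4 arrays each of HCT116 siTOP1 and HCT116 siControl and 2 arrays each of MCF7 siTOP1 and MCF7 siControl. The series design text describes the colon arrays as 2 different samples run as 4 replicates, and no label says whether repeats came from separate cultures. Each cell line had 1 siTOP1 line and 1 control line, so other differences between the stable lines are confounded with the knockdown, and p-values cover only the spread between arrays.

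The deposited values are log2 signals, 1 per probe set and array. The submitters' processing notes name RMA, and its version is not given in the sources used here. The values themselves have another form. They are log2 of linear signals written to 1 decimal, and the mean linear signal of each array, with 2% trimmed at each end, was 499.9. The array medians differed, so the values carry a scaling per array to a common mean near 500 and no quantile normalization across arrays. The tests had been planned for RMA values and were run on the deposited log2 values without a further transformation. In repeat order the array medians were 6.96, 6.95, 6.61 and 6.84 for HCT116 siTOP1, and 7.08, 7.27, 7.02 and 6.82 for HCT116 siControl. They were 7.10 and 7.07 for MCF7 siTOP1, and 7.08 and 7.14 for MCF7 siControl. Detection calls were not used here, and background correction is not given in the sources used here. The number of arrays limits the precision.

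The table held 54675 probe sets, of which 41097 mapped to exactly 1 gene symbol, 1801 to several symbols and 11777 to none. Gene identifiers of 41043 of the first set matched a RefSeq gene table. It served for current symbols, for the order of genes along chromosomes, and for gene length and local gene density. No coordinates are given. Of the probe sets with exactly 1 symbol, the one with the highest mean over the 12 arrays stood for its gene, which gave 19775 genes. A choice between probe sets was made for 10523 of these genes. No filter on signal was applied. The median of all probe set means, 6.88, served as a bound for dim signals, and folds against a group with a mean under it are uncertain in size.

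Genes were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with all 12 arrays in 1 fit and 1 mean per group, so that the 4 groups shared the estimate of spread (8 residual and 1.46 prior degrees of freedom). The contrasts were siTOP1 minus siControl within each line and the difference of these effects, HCT116 minus MCF7. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. TOP1 itself was also compared with exact permutation tests. Overlap between the lines was tested with Fisher's exact test and described with correlations across genes, which are not independent replicates.

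The comparisons, tests, gene lists, rule for naming genes and most alternatives were chosen before the data were examined. The 28 lists were tested with limma's camera at a preset correlation between genes of 0.01, with 56 tests over both lines adjusted together and the tests of the difference between lines adjusted separately. Each list was also tested with an estimated correlation and with fry. List p-values are from camera unless fry is named. The rule named the topoisomerases. It also named, per line, the 10 largest rises and the 10 largest falls among called genes whose siTOP1 and siControl arrays did not overlap and whose higher group mean reached 6.88. Up to 10 genes per direction came from those called in both lines under the same conditions, 5 per direction from the difference between lines, and up to 4 called members from each list described. Loci without a gene symbol were counted and skipped in the naming.

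Repeat numbers are shared between groups. After each group's mean was removed, siTOP1 and siControl arrays of HCT116 with the same number correlated at 0.21 to 0.417 over 12628 genes, and the numbers were also used as a block. All pairs from the same set of repeats, 1 and 2 or 3 and 4, correlated at 0.21 to 0.523, and pairs from different sets at -0.469 to -0.291. Differences between repeats 1 and 2 correlated at -0.012 across siTOP1 and siControl, and those between repeats 3 and 4 at -0.256. A shared number therefore showed no pairing beyond the shared set of repeats. In MCF7 the same-number correlation was 0.01. Values with the repeat number as a block stand beside the results they change.

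Runs of neighbouring genes were examined on the autosomes with the median log2 fold change in sliding windows of 50 measured genes, relative to all genes, for 18991 genes with a position. The threshold came from the largest window in each of 10000 random gene orders. The pipeline was tested on simulated data with 100 planted genes per fold in each line. It recovered 47% of 2-fold and 71% of 4-fold changes in HCT116 with 5 false calls, and 25% and 46% in MCF7 with 3 false calls. The simulated noise was independent between arrays, without the sets of repeats seen in HCT116, so these rates need not hold for the real arrays. A planted list had an adjusted p of 1.2e-20, with 1 other list called, and 51 of 60 genes in a planted run were covered.

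Alternatives covered the choice and averaging of probe sets, filters on dim genes, quantile normalization, median centring, array weights, a variance trend, separate fits per line, blocks and averaging for the HCT116 repeats, stricter thresholds and leaving out each array. Probe sets without a symbol or with several symbols were left out of the gene tests because they name no single gene. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.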

Results

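Transcript levels were measured in HCT116 colorectal carcinoma cells and MCF7 breast adenocarcinoma cells that stably carried a hairpin against TOP1 (siTOP1) or a control construct (siControl). TOP1 encodes topoisomerase I, which relaxes supercoiled DNA through a nick in 1 strand. There were 4 arrays per group in HCT116 and 2 per group in MCF7, each holding log2 signals for 54675 probe sets. Array medians ran from 6.61 to 7.27 in HCT116 and from 7.07 to 7.14 in MCF7. Within groups, the signals of different arrays correlated at 0.919 to 0.952 across probe sets, and any pair within a group differed at 54493 or more probe sets.

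The 8 HCT116 arrays parted by knockdown and by repeat number. Repeats 1 and 2 lay apart from repeats 3 and 4 in both groups on the first principal component, which held 36.6% of the variance. The 3′ minus 5′ difference of the ACTB control probe sets averaged 0.15 in repeats 1 and 2 and -0.05 in repeats 3 and 4 (exact permutation p = 0.0286, adjusted p = 0.16). The upper quartile of the signals was 0.14 lower in HCT116 siTOP1 than in HCT116 siControl (8.82 against 8.96; exact permutation p = 0.0286, adjusted p = 0.4). In MCF7 the ACTB difference averaged 0.04 in siTOP1 and 0.17 in siControl. The bioB hybridisation control averaged 8.33 in MCF7 siTOP1 and 8.81 in MCF7 siControl. Neither measure overlapped between these groups (exact permutation p = 0.333 each, the smallest that 2 arrays per group allow). Such differences between the MCF7 arrays are confounded with the knockdown. Of 20 markers of luminal breast lines, 16 were higher in MCF7 than in HCT116 control cells. Of 14 colon line markers, KRT20 alone was called higher in HCT116, and MYB, AGR2 and ASCL2 were higher in MCF7; these 4 genes were named after their values were seen.

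**Figure D1:**
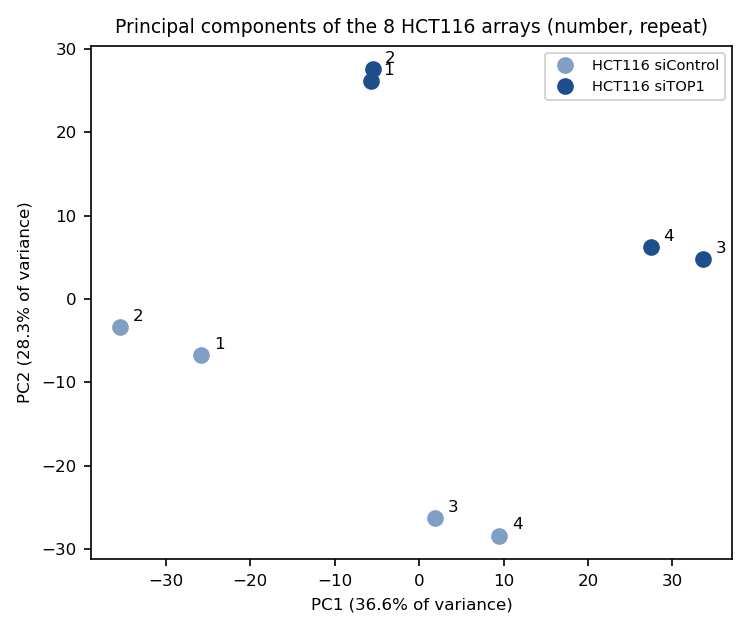
Principal components of the 8 HCT116 arrays, with the first on the horizontal axis (36.6% of variance) and the second on the vertical axis (28.3%), in component units. Each point is an array numbered by its repeat, light for siControl and dark for siTOP1, and repeats 1 and 2 lie left of repeats 3 and 4 within each group.

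The first comparison was of the targeted transcript itself. TOP1 (probe set 208901_s_at) was 2.44-fold lower in HCT116 siTOP1 cells, at 11.86 ± 0.12 against 13.14 ± 0.04 in control cells (mean log2 signal ± SD, n = 4 per group). In MCF7 it was 2.12-fold lower, at 12.05 ± 0.02 against 13.13 ± 0.05 (n = 2 per group). The remaining signal was 41% of control in HCT116 and 47.1% in MCF7. On the log2 scale TOP1 fell by 1.29 in HCT116 (SE 0.084, limma adjusted p = 0.000115) and fell by 1.09 in MCF7 (SE 0.118, adjusted p = 0.00049). The two-sided exact permutation p was 0.0286 in HCT116 and 0.333 in MCF7, each the smallest its number of arrays allows. A second TOP1 probe set, 208900_s_at, was 3.21-fold lower in HCT116 (limma adjusted p = 0.0175 over all probe sets) and 1.92-fold lower in MCF7 (limma adjusted p = 0.215). The TOP1 effect differed between the lines by -0.20 (adjusted p = 0.467). Fitted without the HCT116 arrays, the MCF7 fall had an adjusted p of 0.0631, and with the HCT116 repeats averaged in pairs the HCT116 fall had an adjusted p of 0.11, within limma ranges over the alternatives of 4.33e-06 to 0.215 for MCF7 and 1.25e-07 to 0.126 for HCT116.

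The other topoisomerases were TOP1MT, TOP2A, TOP2B, TOP3A and TOP3B. None of these 5 was called in HCT116, where limma at an unadjusted p under 0.05 also passed TOP1 alone of the 6. In MCF7, TOP2B, a type II enzyme, was 1.45-fold lower (12.04 ± 0.07 against 12.58 ± 0.10, n = 2 per group; adjusted p = 0.0483). TOP3B was 4.03-fold higher in MCF7 (7.62 ± 0.28 against 5.61 ± 1.18; adjusted p = 0.018), from a dim control signal. As a list the 6 genes did not pass camera in HCT116 (adjusted p = 0.254), where 1 was called lower, and 1 adjusted over the list alone. They did not pass camera in MCF7 either (adjusted p = 0.591), with 1 called higher and 2 lower, or 3 lower adjusted over the list alone. By fry the list, which holds TOP1 itself, was lower in HCT116 (adjusted p = 0.000586) and in MCF7 (adjusted p = 0.0149). In MCF7 their mean of 0.12 had the opposite sign to their median of -0.06 and to the test.

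The HCT116 comparison asked which transcripts differ when TOP1 is reduced in colorectal carcinoma cells, and the sterol pathway was lower. Of 18 measured cholesterol synthesis genes, 11 fell and 7 were not called, with 13 lower when adjusted over the list alone. INSIG1, which holds the sterol sensor complex in the endoplasmic reticulum, was 4.27-fold lower (8.85 ± 0.12 against 10.95 ± 0.12, n = 4 per group). STARD4, a sterol carrier protein, was 3.66-fold lower (8.90 ± 0.10 against 10.78 ± 0.06). HSD17B7 and DHCR7, enzymes of late sterol synthesis, were 2.22-fold and 2.14-fold lower. After median centring 4 were called lower and the median was -0.51. The list median was -0.71 (adjusted p = 5.15e-12; adjusted p = 0.00708 with an estimated correlation).

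Genes of the unfolded protein and integrated stress responses were also lower in HCT116. Of 28 measured, 10 fell and 18 were not called, against 12 lower and 1 higher when adjusted over the list alone. SLC7A11, a subunit of the cystine and glutamate exchanger, was 5.46-fold lower (9.30 ± 0.19 against 11.76 ± 0.13). CHAC1, which degrades glutathione, was 2.84-fold lower, DDIT4, an inhibitor of mTOR signalling, 2.72-fold lower, and ASNS, asparagine synthetase, 2.39-fold lower. After median centring 3 were called lower and the median of -0.28 became -0.08. The list had an adjusted p = 0.0015 (adjusted p = 0.0391 with an estimated correlation).

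Ribosome biogenesis genes were higher in HCT116. Of 34 measured nucleolar genes, 7 rose, 1 fell and 26 were not called, with 17 higher and 1 lower when adjusted over the list alone. POLR1E, a subunit of RNA polymerase I, was 1.64-fold higher (11.62 ± 0.07 against 10.90 ± 0.13). NOP16, RRP9 and PES1, which act in ribosomal RNA processing and subunit assembly, were 1.46-fold, 1.43-fold and 1.42-fold higher, PES1 with a limma adjusted p of 0.0676 with the repeat block. Median centring left 4 called, all higher, and raised the median to 0.42. The list median was 0.22 (adjusted p = 6.89e-10; adjusted p = 0.0243 with an estimated correlation).

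Histone genes, splicing factors and apoptosis genes made up the other called lists in HCT116, all with the test upward. Of 15 histone genes, 4 rose, also 4 when adjusted over the list alone, namely H2BC5 (2.44-fold), H1-2 (1.72-fold), H2BC12 (1.66-fold) and H2BC9 (1.58-fold; limma adjusted p = 0.0596 with the repeat block). Their list had a median of 0.16 and an adjusted p of 0.0023, and an adjusted p = 0.269 with an estimated correlation. With repeats 1 and 2 alone its adjusted p was 0.109, within a range of 0.000569 to 0.269 over 22 camera alternatives. Of 23 SR proteins and splicing kinases, SRSF10 alone was called, 1.39-fold higher (limma adjusted p = 0.0632 with the repeat block), with 4 higher and 1 lower when adjusted over the list alone. That list had a median of 0.20 and an adjusted p of 0.0015, against an adjusted p = 0.236 with an estimated correlation and 0.22 after quantile normalization (range 0.000569 to 0.236). Of 34 death receptor, BCL2 family and caspase genes, 2 rose and 1 fell, also when adjusted over the list alone. They were TNFRSF12A, a receptor for TWEAK (1.57-fold higher), BCL2L11, the cell death activator BIM (1.43-fold higher), and CASP10, an initiator caspase (1.70-fold lower), where the repeat block gave the last 2 a limma adjusted p of 0.0536 and 0.0803. The median of this list was 0.09, its mean 0.007 and its camera adjusted p 0.0359. The call was lost in 13 of 22 camera alternatives, including the repeat block (adjusted p = 0.131). It was also lost without siTOP1 repeat 3 (0.0979), siTOP1 repeat 4 (0.0544), siControl repeat 2 (0.146) or siControl repeat 3 (0.0569), and had an adjusted p = 0.171 with an estimated correlation, within a range of 0.0104 to 0.183.

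Among called genes without overlap whose higher group mean reached 6.88, the largest differences in HCT116 were mostly falls toward dim signals. Called genes with both means under that bound were left out here, such as SYTL5, which fell by 3.93 on the log2 scale, more than any gene below. VHRT was 12.6-fold lower, CYP4F11, a cytochrome P450, 10.3-fold, CSTA, a cysteine protease inhibitor, 8.89-fold, and EPHX2, the soluble epoxide hydrolase, 7.16-fold, each with a siTOP1 mean under 6.88. NDRG4, FXYD6, SERPINA5, MXD3 and LRP1B also reached dim signals, where LRP1B fell by 2.52 and NDRG4 fell by 2.87 on the log2 scale. SPARC, a matrix glycoprotein, stayed above that bound and was 5.96-fold lower (8.29 ± 0.26 against 10.87 ± 0.23). Among bright genes that rose, NECTIN3, an adhesion molecule, was 2.56-fold higher (11.32 ± 0.06 against 9.97 ± 0.12). CPA4, a carboxypeptidase, was 2.49-fold higher and RFTN1, a lipid raft protein, 2.40-fold higher. ZDHHC14, a palmitoyltransferase, was 3.04-fold higher (limma adjusted p = 0.124 with the repeat block). KRTAP3-1, ZFP30, TRIML2, FBXO10 and FSTL5 rose from dim control signals, by 1.32 for FSTL5 to 1.87 for KRTAP3-1 on the log2 scale, and the repeat block gave these 5 a limma adjusted p of 0.0533 to 0.0757.

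DNA damage genes did not pass camera as lists in HCT116. Of 24 genes for repair of TOP1 damage, 3 rose and 1 fell (adjusted p = 0.851, with the test downward), with 3 each way when adjusted over the list alone. BLM, a helicase, was 1.35-fold higher, CHEK1, a checkpoint kinase, 1.31-fold higher, and APTX, which clears blocked 5′ ends, 1.22-fold higher. TDP1, which removes TOP1 remnants from DNA, was 1.27-fold lower. None of these 4 kept its call with the repeat block (limma adjusted p of 0.0599, 0.0814, 0.102 and 0.108), nor after median centring. All 4 kept it with repeats 1-2 against 3-4 as a block. Of 31 p53 targets, 1 rose and 6 fell (camera adjusted p = 0.546), with 4 higher and 9 lower when adjusted over the list alone. By fry, which does not compare a list with other genes, the p53 targets were lower (adjusted p = 0.00199). The repair list had a fry adjusted p of 0.178. BAX, an apoptosis effector, was 2.75-fold lower, DDB2, a lesion sensor, 1.57-fold lower (limma adjusted p = 0.0718 with the repeat block), and CYFIP2 1.55-fold lower. After median centring 2 p53 targets were called, both lower. GDF15, a stress cytokine, was 1.97-fold lower by the probe set used, but its difference was 0.11 with probe sets ending _x_at left out.

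In total 1398 genes were called in HCT116 at an adjusted p under 0.05, 499 higher and 899 lower, and 207 of them differed at least 2-fold, 24 higher and 183 lower. At an unadjusted p under 0.05, 4045 of 19775 genes passed. With the repeat number as a block 801 were called. With repeats 1-2 against 3-4 as a block 2593 were called, and all 152 named calls over both lines were kept. With repeats averaged in pairs, as 2 samples per group, 7 were called, and of 71 named HCT116 calls 68 were lost (limma adjusted p of 0.058 to 0.52), with INSIG1, MXD3 and STARD4 kept. In fits chosen after the data were seen, 131 were called within repeats 1 and 2 alone, 50 within repeats 3 and 4 alone, and 27 in both, all 27 in the same direction. Centring each array on its median moved the median of all genes by 0.20, from -0.07 to 0.13, and then 346 genes were called, 64.5% of them higher, against 35.7% without it, so the balance of rises and falls depended on the scaling. Median centring adds this shift to each list's median as well. Without siTOP1 repeat 1, 2 or 3, 929, 923 or 913 genes were called, and without siControl repeat 1 or 2, 835 or 909. With the repeat block 22 of the named HCT116 calls had limma adjusted p of 0.0533 to 0.124 (0.000626 to 0.975 over all alternatives of these genes), those of APTX, BCL2L11, BLM, CASP10, CHEK1, DDB2, FBXO10, FSTL5, GRAMD1C, H2BC9, IFIT1, KRTAP3-1, MVD, NR2F1, PES1, PTGR2, SRSF10, TDP1, TRIML2, VWDE, ZDHHC14 and ZFP30.

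**Figure D2:**
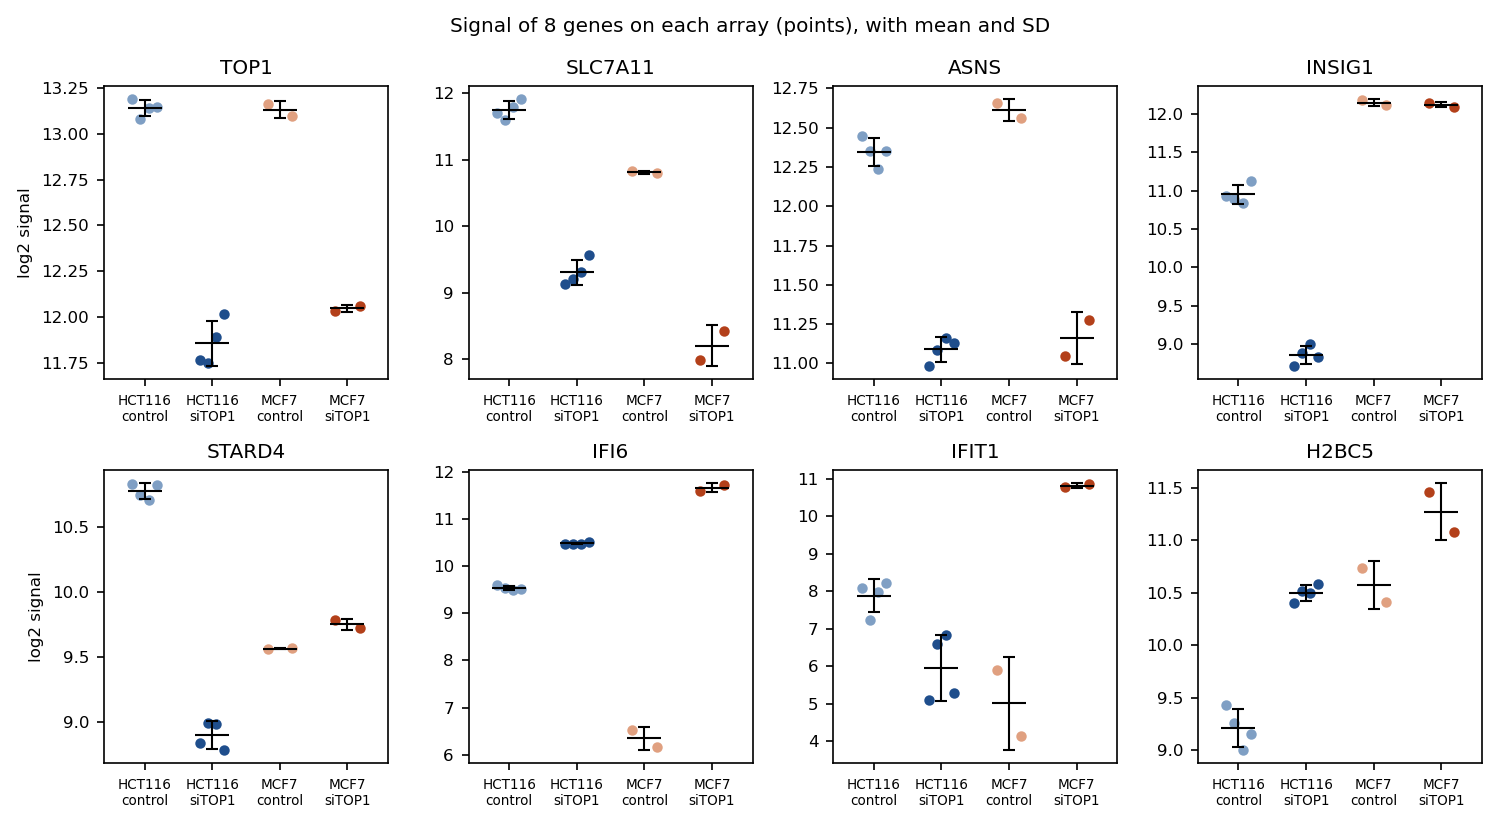
Log2 signal of 8 genes on the vertical axes, for the 4 groups on the horizontal axes. Points are single arrays and black bars the mean and SD (n = 4 per HCT116 group and 2 per MCF7 group). TOP1, SLC7A11 and ASNS were lower with siTOP1 in both lines and INSIG1 and STARD4 in HCT116, while IFI6 and H2BC5 were higher in both. IFIT1 was higher in MCF7 and lower in HCT116 (limma adjusted p = 0.113 in HCT116 with the repeat block).

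The same comparison in MCF7 breast cancer cells showed the largest rises among interferon-stimulated genes. Of 40 measured, 22 rose and 18 were not called, with 27 higher and 1 lower when adjusted over the list alone. IFIT1, an antiviral RNA-binding protein, had a mean of 10.81 ± 0.06 against 5.01 ± 1.24 in control cells (n = 2 per group), and IFI6 11.67 ± 0.09 against 6.34 ± 0.24. IFI27 and IFI44L, also induced by type I interferon, rose by 5.00 and 4.77 on the log2 scale. The control means of these 4 genes were dim, at 2.48 to 6.34, so their folds of 27.3 to 56.0 are uncertain in size. The list median was 1.37 (adjusted p = 2.07e-14; adjusted p = 0.00708 with an estimated correlation).

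Estrogen receptor targets were also called in MCF7 siTOP1 cells. Of 28 measured, 12 rose, 2 fell and 14 were not called, with 14 higher and 2 lower when adjusted over the list alone. IGFBP5, a binding protein of insulin-like growth factors, was 12.8-fold higher (11.25 ± 0.05 against 7.57 ± 0.09). PDZK1, a scaffold protein, was 9.45-fold higher (limma adjusted p = 0.0571 with the repeat block), TFF3, a trefoil peptide, 6.40-fold and CXCL12, a chemokine, 6.06-fold. The falls were of STC2, a secreted glycoprotein (1.75-fold), and of GREB1, a cofactor of the receptor (1.68-fold), the latter named after its values were seen. After median centring 8 were called, all higher. The list median was 0.62 (adjusted p = 0.000202), with an adjusted p = 0.355 with an estimated correlation.

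Histone, sterol, immediate early and DNA replication genes formed the other called lists in MCF7. Of 15 histone genes 5 rose, and 7 when adjusted over the list alone, with H2BC21 2.33-fold (limma adjusted p = 0.0643 with the repeat block), H1-2 2.05-fold, H2AZ2 1.98-fold and H2BC5 1.62-fold higher (list median 0.62, adjusted p = 0.000505). Of 18 cholesterol synthesis genes 4 rose, also 4 when adjusted over the list alone, namely MVD (2.63-fold), PMVK (2.02-fold), TM7SF2 (1.85-fold) and EBP (1.69-fold), all enzymes of the pathway (list median 0.34, adjusted p = 0.0129). Of 23 immediate early genes 6 rose and 2 fell, against 7 and 2 when adjusted over the list alone (list median 0.35, adjusted p = 0.0129). DUSP4, a MAP kinase phosphatase, rose by 4.75 on the log2 scale from a dim control mean of 5.27, and JUN and KLF4, transcription factors, were 3.25-fold and 2.67-fold higher. FOSL1, a partner of JUN, fell by 3.35 to a dim mean of 4.18. Of 49 DNA replication genes 3 rose and 11 fell, against 3 and 14 when adjusted over the list alone (list median -0.20, adjusted p = 0.0023). PRIM2, a primase subunit, was 2.74-fold lower and GINS3, of the replicative helicase, 1.88-fold lower, while LIG1, DNA ligase I, was 1.84-fold higher. CDT1, a licensing factor, was 2.65-fold lower by the probe set used, but its difference was 0.11 with probe sets ending _x_at left out. Median centring left 2 histone and 1 cholesterol synthesis gene called higher, 5 immediate early genes higher and 2 lower, and 1 DNA replication gene higher and 3 lower. Each of these 4 lists had an adjusted p = 0.225 with an estimated correlation.

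Beyond the lists, GOLM1, a Golgi membrane protein, rose by 4.92 and MUC5B, a mucin, by 5.25 on the log2 scale in MCF7 siTOP1 cells. MCRIP1, PPM1J and PADI3 rose by 4.17 to 4.53, PADI3 at the low end and MCRIP1 at the high end. The control means of these 5 genes were dim. The largest named falls were of CORO1A, an actin-binding protein typical of leukocytes, at 4.85 ± 1.52 against 11.01 ± 0.13, and of PYCARD, an inflammasome adaptor, at 3.93 ± 0.76 against 9.26 ± 0.14. NR2F1, an orphan nuclear receptor, was 17.2-fold lower, to a dim mean of 6.51, and BTBD6 11.7-fold lower (7.77 ± 0.10 against 11.31 ± 0.01), BTBD6 without a dim mean. VWDE, HMCN1, ARMCX1 (limma adjusted p = 0.0515 with the repeat block), ROBO1 and SDR42E1 were lower too, at dim signals, where SDR42E1 fell by 3.59 and VWDE fell by 4.52.

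Repair genes, p53 targets and the stress response did not pass camera as lists in MCF7. By fry the p53 targets were higher (adjusted p = 0.0161) and the stress response was lower (adjusted p = 0.000451). The repair list had a fry adjusted p of 0.79. Of 24 genes for repair of TOP1 damage, 1 rose and 3 fell (adjusted p = 0.619), with 2 higher and 3 lower when adjusted over the list alone. ERCC1, a nuclease subunit, was 4.11-fold higher, SPRTN, a protease for DNA-protein crosslinks, 2.76-fold lower, MRE11 1.61-fold lower and TDP2 1.47-fold lower, the last 2 with a limma adjusted p of 0.0891 and 0.103 with the repeat block. Of 31 p53 targets, 5 rose and 3 fell (adjusted p = 0.408), with 6 higher and 3 lower when adjusted over the list alone. TP53INP1 was 2.38-fold higher, BAX 2.35-fold, ACTA2 2.07-fold and PHLDA3 1.81-fold. Of 28 unfolded protein and stress response genes, 1 rose and 7 fell (adjusted p = 0.28), also 1 and 7 when adjusted over the list alone. SLC7A11 was 6.12-fold and ASNS 2.73-fold lower, and SDF2L1, an endoplasmic reticulum chaperone, was 1.95-fold higher. Median centring left 2 repair genes called, 1 each way, 2 p53 targets, both higher, and 2 stress response genes, both lower.

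In MCF7, 2888 genes were called, 1467 higher and 1421 lower, with 1125 of them at least 2-fold different, 582 higher and 543 lower. At an unadjusted p under 0.05, 5193 passed. The call of these genes rested on the spread shared with HCT116: with MCF7 fitted alone limma called 0 genes, although 5515 had an unadjusted p under 0.05. Median centring left 1192 genes called. Without siTOP1 repeat 1 there were 1450, without siControl repeat 1 there were 1551 and without siControl repeat 2 there were 1383. With the repeat block the named MCF7 calls of ARMCX1, GRAMD1C, H2BC21, H2BC9, MRE11, PDZK1, TDP2 and ZDHHC14 had limma adjusted p of 0.0515 to 0.113 (0.00059 to 0.467 over all alternatives of these genes).

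**Figure D3:**
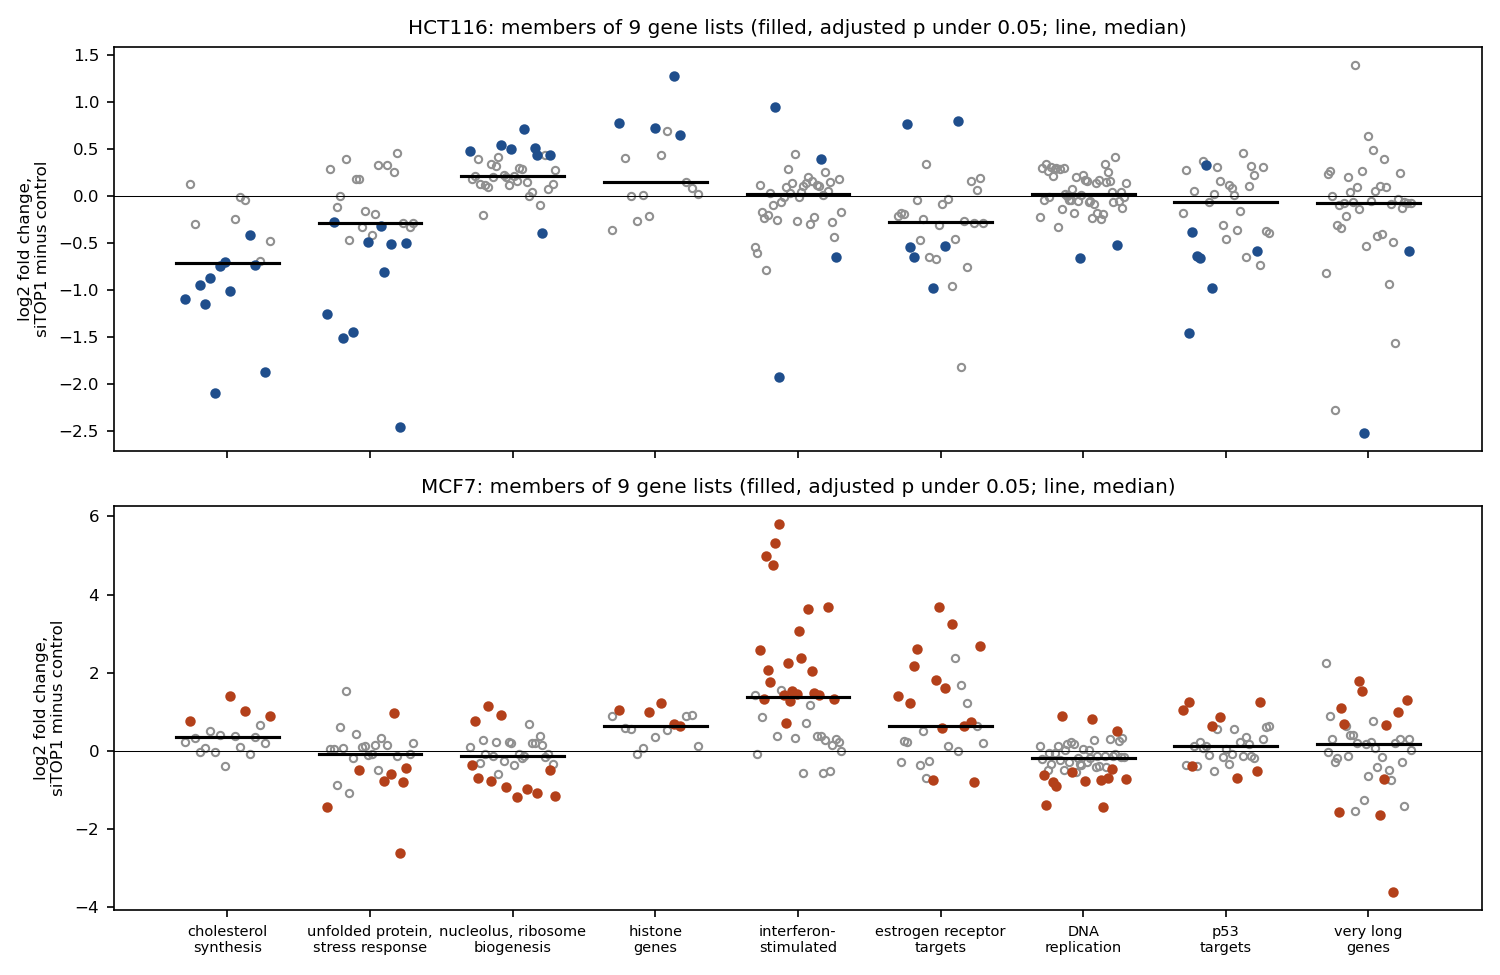
Log2 fold change (siTOP1 minus siControl, vertical axes) of each measured member of 9 gene lists (horizontal axis), with HCT116 above and MCF7 below on different scales. Filled points passed an adjusted p under 0.05, open points did not, and black lines are list medians, such as -0.71 for cholesterol synthesis in HCT116 and 1.37 for interferon-stimulated genes in MCF7; median centring adds 0.20 to each HCT116 difference, and with it or quantile normalization 16 of all 28 HCT116 medians, all of uncalled lists, change sign.

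Some genes moved together in both lines. SLC7A11 fell by 2.45 in HCT116 and by 2.61 in MCF7 on the log2 scale, and ASNS by 1.26 and 1.45. CTH, which makes cysteine from cystathionine, was 2.71-fold and 2.14-fold lower, and PIR, an iron-binding nuclear protein, 2.28-fold and 2.57-fold lower. OGFRL1, PTGR2, DUXAP10, GRAMD1C, SESTD1 and LINGO1 were lower in both lines too, but with the repeat block PTGR2 (limma adjusted p = 0.0722 in HCT116) and GRAMD1C (0.0741 in HCT116 and 0.0819 in MCF7) lost calls. S100A10 and S100A11, partners of annexins, were higher in both, S100A10 by 1.91-fold in HCT116 and 2.61-fold in MCF7. Among the others called higher in both were CAV1, the main caveolar coat protein (1.70-fold and 2.35-fold), SVIL, an actin-binding protein (1.73-fold and 2.26-fold), and FHL2, a LIM domain cofactor (1.83-fold and 3.66-fold). PITX1, PIP4K2A, IFI6 and the histone genes H1-2 and H2BC12L completed the named rises.

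Altogether 223 genes were called in the same direction in both lines, against 101.6 for independent sets. Of these, 90 were higher in both, with 37 expected (Fisher's exact p = 2.53e-15), and the rest were lower in both, with 64.6 expected (exact p = 6.41e-16). Opposite calls were 92 genes higher in HCT116 and lower in MCF7 (35.9 expected, Fisher's exact p = 3.16e-17) and 155 the other way (66.7 expected, exact p = 1.12e-23). In opposite directions there were 247 in total, with 102.6 expected. The 4 odds ratios were alike, at 2.37 to 3.05. Both comparisons used 1 estimate of spread per gene, so their calls are not independent sets and the expected counts are no values for an absent effect. Across all genes, which are not independent replicates, the log2 fold changes of the lines had a Pearson r of -0.016 and a Spearman rho of -0.024. Among the 470 genes called in both, r was -0.018 and rho -0.013. With the HCT116 repeats averaged in pairs 1 gene was called in the same direction, and limma called 0 with each line fitted alone, as MCF7 alone gave 0 (5515 at an unadjusted p under 0.05). With the repeat block there were 120, with the mean of all probe sets 116, and with repeats 1-2 against 3-4 as a block 470. Leaving out HCT116 siTOP1 repeat 1 gave 54 higher and 79 lower. Leaving out HCT116 siTOP1 repeat 2 gave 139, siControl repeat 1 gave 144, MCF7 siTOP1 repeat 1 gave 126, and MCF7 siControl repeat 1 or 2 gave 123 or 109. With the arrays centred there were 48.

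**Figure D4:**
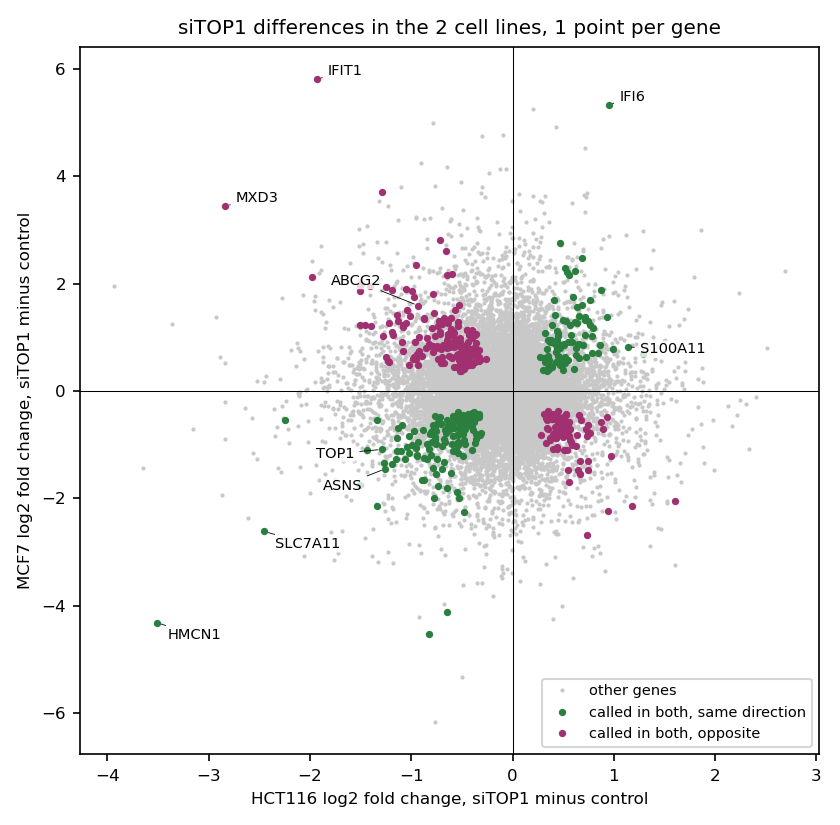
Log2 fold change (siTOP1 minus siControl) of each of 19775 genes in HCT116 (horizontal axis) and MCF7 (vertical axis). Green points are the 223 genes called in both lines in the same direction, purple points the 247 called in opposite directions, grey points all others; the cloud shows no slope (r = -0.016).

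The difference between the lines was tested directly as HCT116 effect minus MCF7 effect. MXD3, a transcriptional repressor that pairs with MAX, was 7.13-fold lower in HCT116 and 10.9-fold higher in MCF7, a difference of -6.28, with a dim lower group in each line. IFIT1 had the largest difference below 0, at -7.73, and was called lower in HCT116 (limma adjusted p = 0.113 with the repeat block) and higher in MCF7. SYTL5 (-5.89), IFI27 (-5.79) and PPM1J (-5.15) followed. CORO1A (5.40), PYCARD (4.83), ABCC4, FOSL1 and GJB2, a gap junction protein, had the largest differences above 0, where the MCF7 fall exceeded the HCT116 effect. ABCG2, an efflux pump that carries camptothecin derivatives, was 1.91-fold lower in HCT116 and 3.01-fold higher in MCF7 (difference -2.52).

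Of the lists, the effect on interferon-stimulated genes was lower in HCT116 than in MCF7 (adjusted p = 3.14e-11), with 21 of 40 members called lower. Cholesterol synthesis was lower in HCT116 as well (adjusted p = 2.28e-10; 12 of 18 called lower). Both had an adjusted p = 0.00869 with an estimated correlation. The estrogen receptor targets (adjusted p = 6.54e-05; 11 lower), immediate early genes (0.016; 2 higher and 8 lower) and MCF7 identity genes (0.042; 4 lower) were lower in HCT116 too. Nucleolar genes (2.92e-05; 12 higher and 2 lower), DNA replication genes (0.000191; 14 higher and 3 lower) and SR proteins (0.016; 3 higher and 2 lower) were higher in HCT116. With an estimated correlation the adjusted p of these 6 lists, in the order given, was 0.307, 0.189, 0.307, 0.0869, 0.0875 and 0.316. Over all genes 2718 differed between the lines, 1153 with a higher and 1565 with a lower effect in HCT116, 1401 of them at least 2-fold. With the HCT116 repeats averaged in pairs 503 differed. Centred arrays gave 927, and leaving out MCF7 siTOP1 repeat 1, siControl repeat 1 or siControl repeat 2 gave 1494, 1534 or 1455.

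Neighbouring genes shifted together in MCF7. Windows of 50 genes passed the threshold of 0.451 on 10 chromosomes, with higher medians on chromosomes 1 (0.482), 5 (0.49), 11 (0.682), 19 (0.508) and 20 (0.462). Lower medians were found on chromosomes 3 (-0.459), 4 (-0.488), 10 (-0.468), 12 (-0.521) and 13 (-0.588). The highest window ran from CIMAP1A to MOB2 on chromosome 11 (permutation p = 0.0001, the smallest that 10000 orders can give), and the lowest from KBTBD6 to MED4 on chromosome 13 (permutation p = 0.0007). These windows held 5.8% of the genes and 10% of the called genes, 279 of 2793. With windows of 25 genes 6 chromosomes passed, and their windows held 1.4% of the genes and 3.3% of the called genes. With windows of 100 genes 13 passed (16.2% and 22.5%), and with genes at or above the median of all probe sets 12 (13.5% and 21.3%). The windows were chosen by the same fold changes, which alone raises the share of called genes. Random gene orders also ignore shared regulation of neighbours. Of the 22 interferon-stimulated genes called higher in MCF7, 5 lay in windows with higher medians. In HCT116 no chromosome passed a threshold of 0.296, the most extreme window being -0.264 on chromosome 5 (permutation p = 0.247).

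**Figure D5:**
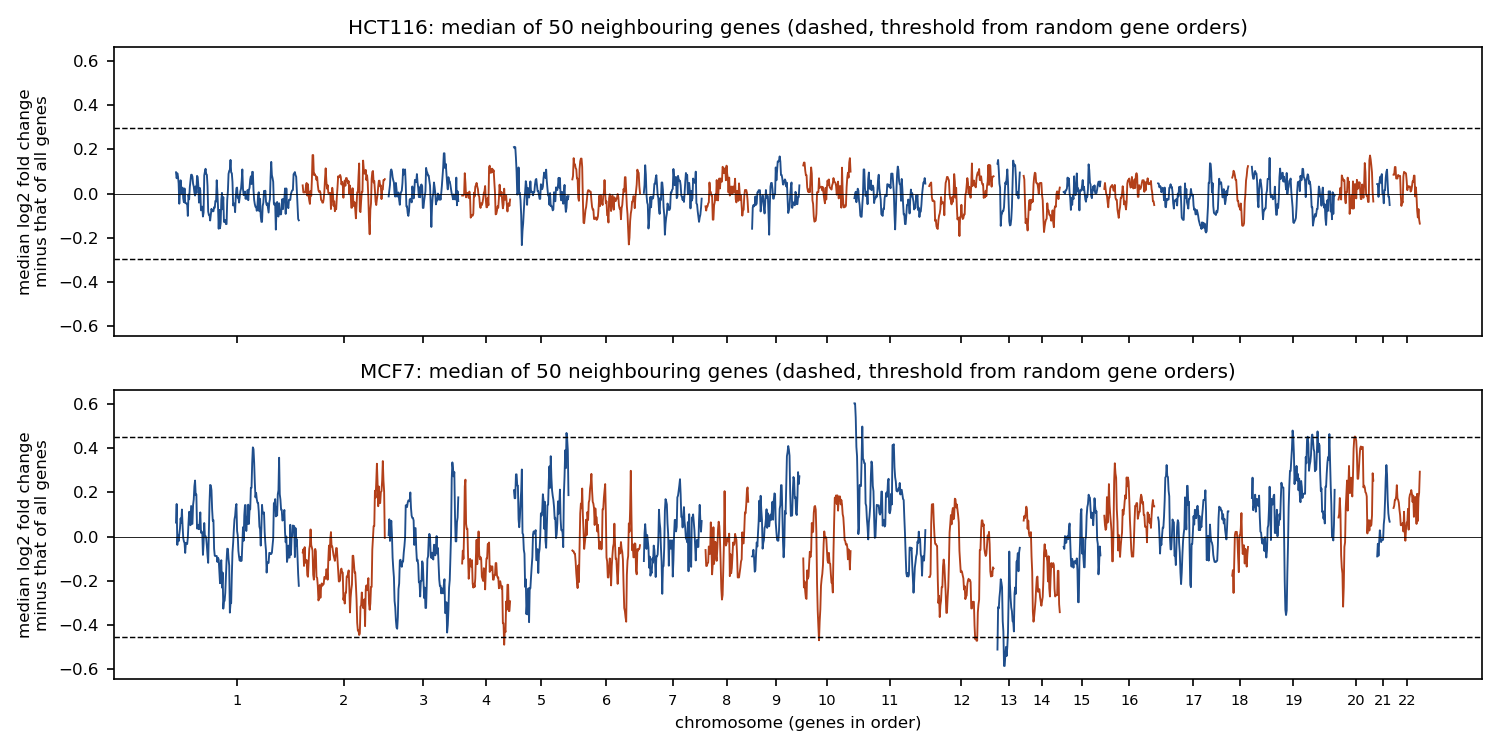
Median log2 fold change of 50 neighbouring genes minus that of all genes (vertical axes), for genes in order along chromosomes 1 to 22 (horizontal axis), drawn at every 10th gene. Colours alternate between chromosomes and dashed lines mark the thresholds from random gene orders (0.296 in HCT116, 0.451 in MCF7), passed in MCF7 alone.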

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

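The tests of leukocytes, of independent differences between the lines (with and without SLC7A11 and ASNS), of HCT116 repeats 1 and 2 against 3 and 4 for the stress genes, and of the scaling of SLC7A11 and ASNS were chosen after the result was seen, as were the fits on some repeats alone.

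The number of genes called in HCT116 was compared with other splits of the same 8 arrays. Of the 35 splits into groups of 4, 2 called at least as many genes as the real one, the real one itself included. That is 5.7%, so chance could not be excluded in this way. The real split called 1398 genes and the highest of the others 1452. That other split set repeats 1 and 2 against repeats 3 and 4, a structure of the samples that the labels do not name. Every remaining split called 3 genes or fewer. Of the 8 splits that part all 4 repeat numbers, the real one called 1398 and the highest other 0. With repeats 1-2 against 3-4 as a block, 18 splits were possible, too few for a share under 0.05; the real one called 2593 genes and the highest other 3.

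In MCF7, 2888 genes were called and genes shifted in runs along 10 chromosomes. The bioB hybridisation control also parted the MCF7 groups (8.33 in siTOP1 against 8.81 in siControl). A difference in array handling is confounded with the knockdown, and its bearing on these calls was not tested. A spread borrowed from HCT116 that is too small for MCF7 would need a larger residual SD in MCF7, but the ratio of the medians, MCF7 to HCT116, was 0.606, where equal spread would give 0.884. The root of the ratio of mean variances was 0.861. The HCT116 spread includes the difference between the sets of repeats, and no label says whether the MCF7 repeats were separate cultures. Both ratios therefore describe arrays over all genes and cannot decide for single genes or for spread between cultures. A copy number difference between the siTOP1 and control lines may contribute and stays open: the shifted windows held 10% of the called genes with a position, at the bound set in advance, but were chosen by the same fold changes, so their excess over 5.8% of all genes is no support, and no DNA was measured. With windows of 25 genes, windows of 100 and genes at or above the median these shares were 3.3% against 1.4%, 22.5% against 16.2% and 21.3% against 13.5%. A trend with gene length and local gene density may contribute too: after its removal, windows on 5 chromosomes passed, 4 of the 10 (5, 11, 13 and 20) and chromosome 2, which passed only then, between the bounds set for and against it, and the knockdown itself, confounded with the line, stays open, as untested.

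Interferon-stimulated genes rose in MCF7 siTOP1 cells, with a list median of 1.37. Leukocytes in the siTOP1 culture would bring their abundant transcripts, but the leukocyte markers had a median of -0.193 and CORO1A and HLA-DRA were lower by log2 differences of -6.16 and -1.85. Array scaling did not account for the rise, since the lowest list median under quantile normalization and median centring was 1.399. A copy number difference remains open for part of the genes. The 22 called higher lay on 9 chromosomes, and 5 of them (22.7%) lay in shifted windows. That share was under the bound set in advance against copy number, but its upper exact 95% limit of 45.4% was not. The windows were also chosen by the same fold changes, those of these genes included, so the overlap is no support. A response to the hairpin or its vector, to reduced TOP1 or to selection of the line cannot be separated by this design and was not tested.

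In the list of the unfolded protein and stress responses 5 genes (ASNS, PHGDH, PSAT1, SLC7A11 and TRIB3) were called lower in both lines. The list itself did not pass camera in MCF7 (adjusted p = 0.28), though it was lower by fry (adjusted p = 0.000451). Independent differences between the lines may account for the 5 shared falls and stay open: the correlation of the effects over the list (r = 0.65, rho = 0.471) lay at the 99.9 percentile of 10000 matched random lists, but without SLC7A11 and ASNS it was 0.326, at the 93.2 percentile, and random genes lack the shared regulation of a list. The HCT116 medians of the 5 genes were -0.758 within repeats 1 and 2 and -0.852 within repeats 3 and 4, but these genes had been chosen by their calls over all arrays, so the values decide nothing. Array scaling may account for part: all 5 stayed called in both lines under quantile normalization but 2 after centring, as the HCT116 folds of PHGDH (-0.81 to -0.6), PSAT1 (-0.51 to -0.31) and TRIB3 (-0.49 to -0.29) shrank, their MCF7 folds hardly moved (-0.77 to -0.74, -0.61 to -0.58 and -0.44 to -0.42) and every SE grew (PHGDH 0.1 to 0.17 in HCT116 and 0.14 to 0.24 in MCF7). SLC7A11 and ASNS kept log2 differences of -1.052 or lower under both scalings, so scaling did not account for these 2 genes, and a shared effect of the knockdown or its vector was not tested.

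Single arrays lay far from the 3 others of their group in 13 of 250 tests (5.2%), and chance alone gives about 1 in 20. The gap to the nearest array, as a share of the group's range, exceeded Dixon's critical value for 4 arrays in each, and only the HCT116 groups held the 4 arrays that the test needs. In siTOP1 it was 0.912 for ARMCX1, 0.875 for PADI3 and 0.856 for TDP2 (repeat 3), 0.877 for DUXAP10 (repeat 2) and 0.901 for GRAMD1C (repeat 4). In siControl it was 0.899 for ARMCX1, 0.915 for H2AZ2 and 0.869 for SERPINA5 (repeat 2), and 0.905 for MVD, 0.914 for SRSF10 and 0.833 for ZFP30 (repeat 3). It was 0.93 for SYTL5 (repeat 1) and 0.866 for VHRT (repeat 4).

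The siTOP1 effect differed between the lines by the limma interaction test for 72 of the 120 named genes. These genes were named mostly by their effects in the same data, some by this difference itself, which raises the share. Over all genes 2718 of 19775 differed. Among interferon-stimulated and immediate early genes the difference, HCT116 effect minus MCF7 effect on the log2 scale, was -7.73 for IFIT1, -5.79 for IFI27, -4.87 for IFI44L, -4.38 for IFI6, -5.05 for DUSP4, -1.5 for JUN, -1.15 for KLF4 and 4.27 for FOSL1. Among estrogen receptor targets and sterol genes it was -3.99 for IGFBP5, -4.2 for PDZK1, -2.48 for TFF3, -2.63 for CXCL12, -2.07 for INSIG1 and -2.06 for STARD4. It was further -1.21 for HSD17B7, -1.32 for DHCR7, -2.41 for MVD, -1.05 for PMVK and -1.36 for TM7SF2. Among repair, p53, apoptosis and replication genes it was -2.05 for ERCC1, 1.23 for SPRTN, 0.63 for CHEK1, 0.74 for TDP2, -2.04 for TOP3B, -2.69 for BAX, -1.62 for GDF15, -0.87 for DDB2 and -1.98 for TP53INP1. It was further -1.23 for ACTA2, -0.69 for PHLDA3, -1.77 for BCL2L11, -0.74 for TNFRSF12A, -1.16 for CASP10, 1.27 for PRIM2, 1.75 for CDT1, 1.21 for GINS3 and -1.01 for LIG1. Among transporters, stress, nucleolar, splicing and histone genes it was -4.9 for ABCC3, 4.65 for ABCC4, 1.49 for ABCD3, -2.52 for ABCG2, -1.26 for DDIT4, -0.7 for SDF2L1, 0.86 for POLR1E, 1.13 for SRSF10 and -1.2 for H2AZ2. Among the other named genes it was above 0, at 5.4 for CORO1A, 4.83 for PYCARD, 4.09 for GJB2, 3.86 for SDR42E1, 3.7 for VWDE and 3.66 for ZDHHC14. It was further 3.62 for BTBD6, 3.46 for NR2F1, 3.12 for ROBO1, 1.78 for CPA4, 1.74 for NECTIN3 and 0.9 for RFTN1. It was below 0, at -6.28 for MXD3, -5.89 for SYTL5, -5.15 for PPM1J, -5.05 for MUC5B, -4.82 for PADI3, -4.61 for CYP4F11 and -4.49 for GOLM1. It was further -3.81 for MCRIP1, -3.35 for EPHX2, -2.63 for SERPINA5, -2.44 for CSTA, -2.06 for SPARC, -1 for FHL2 and -0.92 for PITX1.

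By camera, 8 lists differed between the lines. The adjusted p of the difference was 3.14e-11 for interferon-stimulated genes, 2.28e-10 for cholesterol synthesis, 2.92e-05 for nucleolar genes and 6.54e-05 for estrogen receptor targets. It was 0.000191 for DNA replication, 0.016 for immediate early genes, 0.016 for SR proteins and splicing kinases and 0.042 for MCF7 identity genes. With an estimated correlation the first 2 stayed called (adjusted p = 0.00869 for each), and the other 6 had an adjusted p of 0.0869 to 0.316.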

How the results depend on the processing

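Fits that used HCT116 repeats 1 and 2 or 3 and 4 alone, the filter at the median together with repeats 1-2 against 3-4 as a block, and that block on averaged repeats were chosen after seeing the data. Of the named genes' values under the alternatives, 5632 kept direction and side of the threshold, 762 lost a call, 76 gained one and 4 reversed. Without probe sets ending _x_at the difference was 0.106 for GDF15 in HCT116, -0.742 for GDF15 in MCF7 and 0.111 for CDT1 in MCF7, and with the mean of all probe sets -0.254 for GDF15 in MCF7. Those settings use other probe sets of the gene. Of 152 named calls, between 60 (each line fitted alone) and 152 (repeats 1-2 against 3-4 as a block) were kept where all 152 had a value. With the HCT116 repeats averaged in pairs 79 were lost, 68 of 71 in HCT116 and 11 of 81 in MCF7, and with the block added 81, 71 in HCT116 and 10 in MCF7. List tests kept their side in 1229 cases, gained a call in 37 and lost one in 22. The HCT116 cholesterol, nucleolar and stress response lists and the MCF7 interferon list kept their calls under all 22 camera alternatives (highest adjusted p 0.00708, 0.0243, 0.0391 and 0.00708). Among the named genes and the list tests, the repeat block changed 1 call that the report does not name, gained by TP53INP1 in HCT116, while it took the MCF7 count from 2888 to 2503 and the count for the difference from 2718 to 2245. The lowest adjusted p over the camera alternatives was 9.14e-06 for the MCF7 estrogen receptor list, 9.32e-05 for the histone list, 0.00641 for the immediate early list, 0.000863 for the DNA replication list and 0.0078 for the cholesterol list. The cause was not tested where none is given.

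The HCT116 count of 1398 became 801 with the mean of all probe sets, 2141 and 2126 with genes at or above the median and above the upper quartile, 346 with centring, 867 fitted alone and 801 with the repeat block. It became 2593 with repeats 1-2 against 3-4 as a block, and 3524 with that block and the filter. It was 7 with repeats averaged in pairs, which leaves fewer samples, and limma called 0 when the block was added (3178 at an unadjusted p under 0.05). It was 131 and 50 within repeats 1 and 2 or 3 and 4 alone, 423 at an adjusted p under 0.01 and 207 at 2-fold. The MCF7 count of 2888 became 1192 with centring, 1851 with averaged repeats, 4915 with block and filter, 1390 at 0.01 and 1125 at 2-fold. Fitted alone limma called 0, with 5515 at an unadjusted p under 0.05 and few degrees of freedom. The count of 2718 genes that differed between the lines became 1682 with the mean of probe sets, 927 with centring, 503 with averaged repeats, 946 with averaged repeats and the block, and 1779 with repeats 3 and 4 alone. It was 4802 with block and filter, 1130 at 0.01 and 1401 at 2-fold.

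Genes called in both lines in the same direction, 223 in the report, became 116 with the mean of probe sets, 422 and 468 with the filters, 48 with centring and 373 with trend and robust variance. They became 120 with the repeat block, 470 with repeats 1-2 against 3-4 as a block, 787 with that block and the filter, and 1 with averaged repeats. They were 28 with repeats 1 and 2 alone, 11 with repeats 3 and 4 alone, 55 at 0.01 and 15 at 2-fold. There were 0 with each line fitted alone and with averaged repeats and the block, where limma called 0 in MCF7 and in HCT116. TOP1 kept its fall but not its call in MCF7 fitted alone (-1.087), by its other probe set in MCF7 (-0.941), and in HCT116 with averaged repeats (-1.286) and with the block added (-1.286). Lists called, 6 in each line, became 3 in HCT116 and 1 in MCF7 with an estimated correlation, and 13 and 16 with fry, which does not compare a list with other genes. The correlation of the lines across genes was -0.03 with genes at or above the median, and 6 chromosomes passed with windows of 25 genes, against 10. Leaving out 1 array at a time gave 835 to 1192 genes in HCT116, 1383 to 2762 in MCF7, 1455 to 2542 for the difference and 109 to 168 in both lines. It gave TOP1 differences of -1.339 to -1.251 in HCT116 and -1.121 to -1.054 in MCF7, with 5 to 8 lists called in HCT116 and 6 in MCF7. Where this left 1 MCF7 array in a group, that array was assumed to vary like the others. Signal over background limits the folds of genes with a group mean under 6.88.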

Other observations

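No test in this part was chosen after its result was seen. Counts of calls adjusted over the list alone were the same as those over all genes unless another count is given. Transporters of the ABC family moved one by one in MCF7, where 2 of 19 rose and 4 fell (adjusted p = 0.819 for the list, whose median of 0.01 and mean of 0.06 had the opposite sign to the test). ABCC3, a pump for organic anions and bile salts, had a mean of 9.53 ± 0.10 in siTOP1 cells against a dim 5.72 ± 0.99 in control cells (n = 2 per group). ABCC4, which exports cyclic nucleotides, had 4.33 ± 1.35 against 8.58 ± 0.32, and ABCD3, of the peroxisome, was 2.85-fold lower. In HCT116 5 ABC genes fell, ABCG2 among them, and 6 when adjusted over the list alone (list adjusted p = 0.0987). Death receptor, BCL2 family and caspase genes had 7 rises and 4 falls among 34 in MCF7, against 8 and 5 when adjusted over the list alone, where BCL2L11 was 4.87-fold and TNFRSF12A 2.62-fold higher (adjusted p = 0.796; median -0.15 and mean 0.02, with the test upward). Among very long genes, 7 rose and 4 fell of 39 in MCF7 (adjusted p = 0.512; median 0.16 and mean -0.001), ROBO1, an axon guidance receptor, among the falls, while 2 fell in HCT116 (adjusted p = 0.851), LRP1B among them.

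Hypoxia and glycolysis genes had 5 falls among 27 in HCT116 (1 rise and 6 falls adjusted over the list alone; adjusted p = 0.583; median 0.004 and mean -0.16, with the test downward) and 1 rise and 6 falls in MCF7 (7 falls adjusted over the list alone; adjusted p = 0.184). Nucleolar genes, higher in HCT116, had 3 rises and 9 falls in MCF7 (10 falls adjusted over the list alone; adjusted p = 0.133). SR proteins and splicing kinases had 3 falls in MCF7 (adjusted p = 0.357). Interferon-stimulated genes had 2 rises, IFI6 among them, and 2 falls in HCT116 (adjusted p = 0.593, median 0.02 and mean -0.08, with the test upward). IFIT1 was among the falls, with a limma adjusted p of 0.113 with the repeat block. Estrogen receptor targets had 2 rises and 4 falls in HCT116 (5 falls adjusted over the list alone; adjusted p = 0.0632). Epithelial junction and keratin genes had 2 rises and 7 falls among 28 in HCT116 (8 falls adjusted over the list alone; adjusted p = 0.315) and 2 rises and 3 falls in MCF7 (3 rises adjusted over the list alone; 0.28; median 0.21, with the test upward). Mesenchymal and matrix genes had 1 rise and 1 fall, SPARC, among 31 in HCT116 (0.851; median -0.08 and mean -0.16, with the test upward) and 1 rise in MCF7 (0.874; median -0.07 and mean 0.04, with the test downward).

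Mitosis genes had 4 falls among 38 in HCT116 (7 adjusted over the list alone; adjusted p = 0.0952) and 5 rises and 4 falls in MCF7 (10 and 9 adjusted over the list alone; 0.874; median -0.11, with the test downward). DNA replication genes had 2 falls in HCT116 (0.0632; median 0.03 and mean 0.04, with the test upward, and 10 higher and 3 lower at an unadjusted p under 0.05). Homologous recombination and Fanconi genes had 1 fall among 19 in HCT116 (0 by limma adjusted over the list alone; 0.793) and 2 in MCF7 (1 rise and 3 falls adjusted over the list alone; 0.373). Heat shock genes had 1 rise and 1 fall among 13 in HCT116 (0.17) and 3 falls in MCF7 (0.357). Immediate early genes had 1 rise and 2 falls in HCT116 (2 and 4 adjusted over the list alone; 0.851). Wnt targets had 3 rises among 22 in HCT116 (0.316) and 2 rises and 1 fall in MCF7 (0.796). Of 23 NF-kB targets, limma called 2 lower in MCF7 (0.796; median 0.19 and mean 0.14, with the test upward) and 0 in HCT116 (0.793), where 1 was higher and 1 lower at an unadjusted p under 0.05. Cancer-testis genes had 1 fall among 15 in HCT116 (0.851) and 0 calls by limma in MCF7 (0.512), also 0 at an unadjusted p under 0.05.

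Markers of other cell types and of the lines themselves were measured in the same way. Of 12 fibroblast markers limma called 0 in HCT116 (adjusted p = 0.983; 0 at an unadjusted p under 0.05) and 0 in MCF7 (0.851; 1 higher at an unadjusted p under 0.05; median -0.01 and mean 0.12, with the test upward). Of 15 leukocyte markers limma called 0 in HCT116 (0.932; 1 higher and 1 lower at an unadjusted p under 0.05) and 2 lower in MCF7 (0.362). HCT116 identity genes had 2 falls among 14 in HCT116 (0.462) and 2 rises in MCF7 (0.512). MCF7 identity genes had 2 falls among 20 in HCT116 (3 adjusted over the list alone; 0.365) and 4 rises and 1 fall in MCF7 (5 rises adjusted over the list alone; 0.122). In each line 22 lists were not called by camera, and median centring would add 0.20 to each of their medians in HCT116 and 0.03 in MCF7.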
